A study of Mus musculus with 5 samples.

How the data were processed

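Whole-genome expression was measured in 3T3-Swiss albino cells, a mouse fibroblast line, cultured on 5 chemically treated surfaces. Each surface type is 1 sample. Per the series' design text, each sample is RNA pooled from 3 surfaces of 1.25 cm by 1.25 cm and was hybridized 4 times. Per the labels' protocols, RNA was amplified with T7 primers after spike-in RNA had been added, surface RNA was labelled with Cy5, and RNA from cells in a standard culture flask was labelled with Cy3. The dyes were oriented in this way on every array, with no dye swap in the labels. A dye effect therefore stays in each comparison with the flask. It cancels in a difference between surfaces only as far as it was alike on their arrays, which was not examined.

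Groups were taken from the sample labels. The fibronectin sample spent 24 h on a patterned fibronectin surface. The dynamic samples spent 12 h on a fibronectin pattern, 2 h in the chemical step that immobilized linear or cyclic RGD peptide with cells present, and 24 h on the RGD surface. The non-dynamic samples were seeded on linear or cyclic RGD and spent 24 h there. Because each group holds 1 sample, differences between single surfaces were called by size alone, with no p-value. After the data were seen, limma's moderated test with Benjamini-Hochberg adjustment was added for fits that pool surfaces. These set dynamic against non-dynamic RGD over both peptides, linear against cyclic RGD over both exposures, each without and with the other factor as a block, and the 3 surfaces begun on fibronectin against the other 2. Such fits treat different surfaces as replicates, so their spread includes any interaction, and the p-values measure only the spread between these samples. Some genes had a residual variance of 0 in these fits, the deposited ratios having 2 decimals.

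Scanner files were used for 1 sample, non-dynamic linear RGD, as 4 files with 1 hybridization each. Per the file headers, these were made by Agilent Feature Extraction 9.5.1.1, whereas version 9.5.3 is given per the submitters' processing notes. The spot brightness and the brightness around each spot are intensity values, not normalized, per the file headers. The processed signals are intensity values that the scanner software had background-subtracted, detrended in space and dye-normalized by a linear and a lowess step, per the file headers. The log ratio is the log10 of Cy5 over Cy3 processed signal, per the file headers. It equalled the log10 of the 2 processed signals within 0.001 on 90.5% of spots. Scanner files of the other 4 samples were not used here, so their slides, scan days and signal over background are not known here.

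For all 5 samples the deposited series table gave 1 value per probe, which proved to be a linear ratio of surface over flask with 2 decimals and a floor of 0.01. The authors' scale and direction are not stated in the sources used here and were found by setting the non-dynamic linear RGD column against its scanner values. The log2 of that column correlated at 0.93 across measured genes with the log2 ratios computed here and at 0.99 with the mean log ratio of the scanner software, with a slope of 1.20 on the former. For the other 4 columns the same scale and direction were assumed from that match and from the dyes in the labels. How the authors normalized the arrays, combined the 4 hybridizations and chose the probes left blank is not given in the sources used here. Column medians were 1.0 for fibronectin and dynamic linear RGD and 1.01 for the other 3 columns, so the columns were centred close to a ratio of 1. Blank probes numbered 1915 for fibronectin, 2401 for dynamic linear, 2081 for dynamic cyclic, 2488 for non-dynamic linear and 2832 for non-dynamic cyclic RGD, of which at most 14 were measured probes. Values at the floor numbered 35 to 50 per column, at most 1 of them on a measured probe. With 2 decimals, strongly lowered genes carry coarse values. No column of the series table was left unused.

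Scanner values were computed in R 4.3.3 with limma 3.58.1. Background was corrected by normexp with an offset of 50 on mean signal and median local background, and each array was normalized by loess with a span of 0.3, control spots having weight 0. Outlier spots, 159 to 246 of 45018 per array, and the 1639 control spots were then left out. Spots of a probe were averaged, and the 4 hybridizations were averaged as 1 replicate. Their SD is technical. Further steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

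Of 41174 probes, 25510 carried a RefSeq accession, and 22944 of these were named through a reference gene table of assembly GRCm38.p6, matched without version numbers. Other probes kept the file's own gene name, which can be old. In all, 34461 probes named 22212 genes. A gene counted as measured when at least 1 of its probes was well above background in either channel on at least 3 of the 4 scanned arrays, and its value is the mean over such probes. This held for 34124 probes and 19574 genes, and 19565 genes had a value in every comparison. Detection on the other surfaces was judged on these same arrays. On 5 genes, probes lay past 2-fold in opposite directions. For 37 measured genes a hybridization lacked a value.

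Signal over background limited precision. On the scanned arrays 82.8% to 84.6% of probes were well above background in the surface channel and 74.1% to 77.5% in the flask channel, with a median mean signal of 218 to 242 and 207 to 226 over a background of 46 to 48. At most 1 probe was saturated. Where a gene was not well above background in the dimmer channel on all 4 arrays, its fold is given as "at least", computed after quantile scaling of the average intensities against the higher of the lowest well-detected signal and its own signal.

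A gene was called past 2-fold at an absolute log2 of at least 1, and for scanner values the sign also had to be the same in all 4 hybridizations. Differences between surfaces were taken between log2 deposited ratios. Genes were named by a rule fixed before the data were examined. It took the 8 highest and 8 lowest measured genes past 2-fold per surface, the 6 highest and 6 lowest per difference, and for all 5 surfaces together the 8 higher and 8 lower genes with the largest smallest-of-5 change. Clone, locus and accession names were passed over. It also took up to 4 members of each gene list with the largest change, and always the 9 RGD-binding integrin subunits, Fn1 and the reference genes Actb and Gapdh where measured. No measured probe was named Gapdh. Gene lists, 37 in number, were fixed before the data were examined and covered integrins, adhesion, matrix, contractile, growth, stress, inflammatory and signalling genes, housekeeping genes, and markers of fibroblasts and of other cell types. For each list the median log2 was set against 10000 random lists of the same size matched on mean array signal in 20 bins. Such a percentile describes these samples and is no test. The result of 1 list is not reported here.

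Comparisons that share the flask share its chance values, so overlaps and correlations are given beside 100 simulations of unchanged surfaces with a shared flask, whose spread per gene was the SD between the 5 surfaces and so includes their differences, and beside the overlap of independent lists. The simulated flask was assumed to have that same spread, which by itself fixes the simulated correlation at 0.50. Correlations of differences carry an interval from 200 bootstrap draws over genes at 95%, although genes are not independent.

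The steps were tested on simulated data for non-dynamic linear RGD against the flask. On 43379 spots, a simulated log2 of 2 was called in 100% and one of -2 in 73.5% of changed spots, with median recovered values of 1.82 and -1.52. A simulated 1 was called in 27.3% and a simulated -1 in 17.6%, and 0 of 43179 unchanged spots were called. In this simulation falls were recovered smaller and called less often than rises. On 19574 genes, the size call found 50 of 50 genes at each of -2, -1.5, 1.5 and 2, and 0 of 19374 unchanged genes. Of 20 simulated lists with a shift of 0, 0.2 and 0.5, the median lay outside the central 95% of random lists for 3, 19 and 20. On 19565 simulated genes, the fit of dynamic against non-dynamic RGD without a block called 48 of 50 genes at -1, 47 of 50 at 1 and 27 of 19365 unchanged genes. The fit of linear against cyclic RGD without a block called 0 of 50 at -1 and at 1, 35 of 50 at -2 and 33 of 50 at 2, and with the block 50 of 50 at each size and 40 of 19365 unchanged genes. These simulations hold no interaction and no batch, so they show neither the effect of treating surfaces as replicates nor that of a batch.

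Alternatives numbered 11 for the scanned sample and 6 for the deposited ratios. They covered background correction, normalization, the filter on dim probes, the brightest probe of a gene, the source of the values, centring, quantile normalization and each hybridization left out. Unmatched random lists, no filter and centring were tried for the gene lists, and quantile normalization of the columns was added for the lists after seeing the data, as were the fits that pool surfaces. Averaging within slides was not run, because 1 slide held all 4 scanned arrays.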

Results

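Murine 3T3-Swiss albino fibroblasts were profiled on 5 ligand-bearing surfaces, each against the same cell line grown in a standard culture flask. Fibronectin is a matrix protein that cells bind through integrins, and RGD is the short arginine-glycine-aspartate motif in it that several integrins recognise. The linear peptide carries this motif in an open chain and the cyclic peptide carries it in a ring. On dynamic surfaces, cells attached to a fibronectin pattern for 12 h before RGD was immobilized around them and were harvested after a further 24 h. On non-dynamic surfaces, cells met RGD from the start and were harvested at 24 h. The design thus asks how the transcriptome differs between a protein and a peptide ligand, between linear and cyclic peptide, and between a ligand presented at seeding and one presented to attached cells. Each surface was 1 pooled sample, so a difference between single surfaces has no biological replicate and no test, and tests are given only for fits that pooled surfaces. Values are log2 of surface over flask, or differences of these, and outside the limma fits "higher" or "lower" counts genes past 2-fold among 19574 measured genes.

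Within a surface only technical error could be estimated, and only for non-dynamic linear RGD. Its 4 hybridizations correlated at 0.93 to 0.99, with a median SD per gene of 0.08 and a 95th percentile of 0.21. All 4 shared 1 slide and 1 scan day, so these values and the splits below hold no error between slides or days. Setting hybridizations 1 and 2 against 3 and 4 of this same RNA gave 36 genes past 2-fold, with the central 95% of genes between -0.29 and 0.41. The other splits gave 6 genes each. In the first split list medians lay between -0.08 and 0.19, and 7 of 37 lists stood outside the central 95% of random lists.

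Genes past 2-fold on all 5 surfaces included 3 matrix metalloproteinase genes. Mmp13, an interstitial collagenase, was higher by 3.34 (10.2-fold) on dynamic linear RGD at the least and, in the deposited ratios, 63.9-fold on non-dynamic linear RGD at the most, where the scanner value was 55.4-fold. Mmp3 and Mmp10, both stromelysins, were at least 3.10 and 2.77 higher on every surface. The calgranulin gene S100a8 was at least 2.73 higher and Socs2, a feedback inhibitor of cytokine signalling, at least 2.68. Nmu, encoding neuromedin U, was at least 2.49 higher. Lower on every surface were the neuropeptide gene Vip (-3.18 or lower, at least 9.09-fold), the retinaldehyde dehydrogenase gene Aldh1a1 (-2.56 or lower) and its near-identical paralog Aldh1a7 (-2.25 or lower). Fos, a subunit of the AP-1 transcription factor, was 5.26-fold to 10.0-fold lower, and Ptx3, a secreted pattern-recognition protein, was 4.00-fold to 23.6-fold lower. The keratin gene Krt19, an epithelial marker, was at -2.18 or lower. Kcnj5 (2.69 or higher) and Defb37 (2.68 or higher) were also named, but on the scanned arrays the flask signal of both was not well above background. Sh2d4a (-3.18 or lower) and Ntn4 (-2.25 or lower) had no surface signal well above background there.

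In total 213 genes were past 2-fold in the same direction on all 5 surfaces, 158 higher and 55 lower, of 19565 genes. Independent lists of these sizes would share fewer than 1 gene. Simulated unchanged surfaces that shared only the flask gave a mean of 93.0 genes and at most 117 in 100 simulations. With scanner values for non-dynamic linear RGD the count was 112, and the same simulation with the spread of those values gave a mean of 80.4 and at most 106. The shared reference may therefore account for part of the overlap but in this simulation not for all of it. That holds under its assumption that the flask has the same spread per gene as a surface. The share of a dye effect was not measured.

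**Figure D1:**
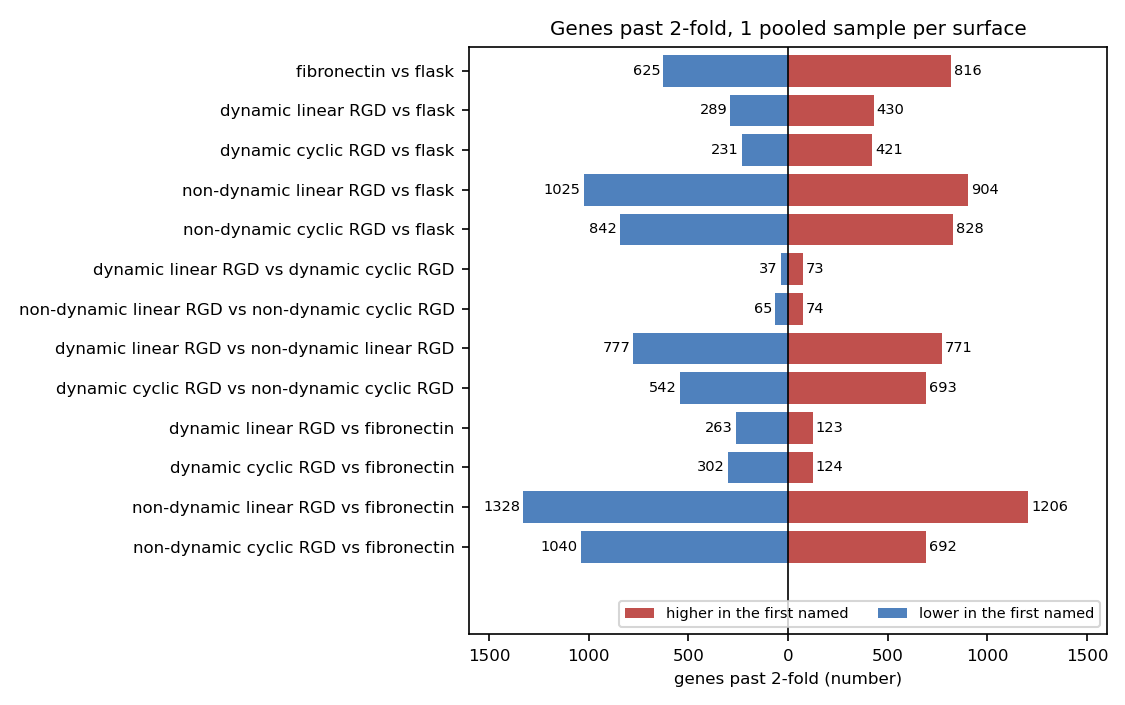
Number of genes past 2-fold, higher and lower as separate bars, for each surface against the flask and for each difference between surfaces (x axis, genes). The largest total was 2534 genes for non-dynamic linear RGD against fibronectin and the smallest was 110 for dynamic linear against dynamic cyclic RGD.

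On fibronectin, the medians of interferon-stimulated genes, matrix proteases and matrix glycoproteins stood above the central 95% of random lists, and those of SRF and YAP targets, contractile genes and focal adhesion components stood below it. Of 25 measured interferon-stimulated genes, 11 were higher and 0 lower (median 0.94), among them Ifi44 (3.30), Oasl2 (3.08), Usp18 (2.35) and the immunoproteasome subunit Psmb8 (2.05). The interferon-inducible GTPase gene Iigp1 was the highest named gene at 4.92 (30.3-fold). Of 23 matrix proteases and inhibitors, 12 were higher and 2 lower (median 1.01), with Mmp13 at 4.35 (20.4-fold), Mmp3 at 4.26 (19.1-fold), Mmp10 at 3.54 and the collagen-degrading cathepsin Ctsk at 2.60. Of 27 matrix glycoproteins and proteoglycans, 8 were higher and 1 lower (median 0.29), including Spp1 (3.30), Postn (2.87), Dcn (2.66) and Lum (2.23). The 16 collagens had a median of 0.49, also above the central 95% of random lists, with 3 higher and 2 lower. Plxdc1 (4.46), the acute-phase gene Hp (4.25), the angiotensinogen gene Agt (4.19), the chemokine gene Ccl8 (4.04) and the iron exporter gene Slc40a1 (3.96) completed the highest genes.

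Of 19 SRF and YAP target genes, which respond to actin tension, 12 were lower on fibronectin and 0 higher (median -1.24), with Amotl2 at -2.40, Thbs1 at -2.22, Vcl at -1.94 and Ajuba at -1.94. Of 20 contractile genes 8 were lower and 0 higher (median -0.67), among them Fhl1 (-2.84), Myl9 (-1.89) and Cnn1 (-1.64). Of 26 focal adhesion components 8 were lower and 0 higher (median -0.64). Among 23 immediate early genes 5 were lower and 0 higher (median -0.69), led by Fos (-3.06) and Fosb (-2.32). The Notch pathway genes Hes1 (-2.94) and Jag1 (-2.44) were lower, but their list as a whole was not. Of 22 Wnt and Notch pathway genes 6 were higher and 4 lower (median 0.26, percentile 98.4 of random lists). The lowest genes were Sh2d4a (-5.64), Vip (-4.32), Ptprq (-3.64), Upk3b (-3.47), Aldh1a1 (-3.32), Sema3e (-3.20), Hey2 (-3.18) and Scel (-3.18). On the scanned arrays, Sh2d4a, Hey2 and Scel had no surface signal well above background and Upk3b had it on 1 array, so these values are uncertain. In all 1441 genes were past 2-fold, 816 higher and 625 lower, but without the filter on dim probes 823 were higher and 1412 lower.

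Fewer genes were past 2-fold against the flask on the dynamic surfaces than on the other surfaces. On dynamic linear RGD 719 genes were past 2-fold (430 higher, 289 lower), and on dynamic cyclic RGD 652 (421 higher, 231 lower). Quantile normalization, which gives the columns 1 distribution and so draws the counts together by construction, gave 1147 and 1140 against 1148 on fibronectin. Without the filter on dim probes lower genes outnumbered higher ones (442 higher and 1077 lower, 429 higher and 932 lower). Of 25 interferon-stimulated genes, 7 were higher on dynamic linear (median 0.32) and 8 on dynamic cyclic RGD (median 0.41), with 0 lower on either. Oasl2 stood at 2.27 and 2.35, Ifi44 at 2.06 and 2.63, Usp18 at 2.01 on both, and Iigp1 at 3.81 and 3.56. Of 23 proteases and inhibitors 8 were higher and 2 lower on each (medians 0.54 and 0.67), Mmp3 reaching 3.61 and 3.70 and Mmp13 3.34 and 3.82. Periostin (Postn) stood at 2.39 and 2.49, osteopontin (Spp1) at 2.32 and 2.44, and the collagen gene Col18a1 at 1.91 and 1.78.

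Genes of cholesterol biosynthesis had medians of -0.58 on dynamic linear and -0.54 on dynamic cyclic RGD, below the central 95% of random lists, with 2 and 1 of 22 members past 2-fold and lower. The list was as low on non-dynamic cyclic RGD (median -0.54, 4 lower, 0 higher), so this was no feature of the dynamic surfaces alone. Mvk, encoding mevalonate kinase, stood at -1.20 and -1.01, and Lss, encoding lanosterol synthase, was at -1.04 on dynamic linear RGD. SRF and YAP targets were closer to the flask than on fibronectin, with medians of -0.23 and -0.36. Immediate early genes had medians of -0.30 and -0.49, with 3 and 5 members lower and 0 higher, Fos at -2.40 and -2.74. Agt (3.53 and 3.44), Sprr2d (3.46 and 3.24) and Pi15 (3.18 and 3.53) were among the highest genes of both dynamic surfaces. Dcn (3.23) and Ccl8 (2.98) were named on dynamic linear, and Hp (2.91) on dynamic cyclic RGD, where Socs2 (2.96) was also among the highest. Among the lowest were Vip (-3.18 and -3.32), Aldh1a1 (-2.74 and -2.56) and Ptprq (-3.64, dynamic linear). Mmp12 (-4.06) and Htr1a (-3.84) on dynamic linear RGD had flask signals not well above background on the scanned arrays.

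On non-dynamic linear RGD, the surface with scanner data, 1064 genes were past 2-fold with 1 sign in all 4 hybridizations, 536 higher and 528 lower. Mmp13 was 5.79 higher (55.4-fold, SD 0.03 over 4 hybridizations), Mmp10 4.53 (23.2-fold) and the EGF receptor ligand Areg 3.65 (12.6-fold). Foxf2 (3.53), Akr1c18 (3.52), the phosphatase gene Ptpn22 (3.51) and the near-identical prolactin family genes Prl2c3 (3.56) and Prl2c5 (3.42) followed. The lowest genes were Ptx3 (-3.89, 14.8-fold lower, SD 0.09), Vip (-3.62, 12.3-fold lower), the aggrecanase gene Adamts5 (-3.33, 10.0-fold lower) and Fos (-3.04, 8.21-fold lower). Aldh1a1 (-3.02), the growth factor signalling inhibitor Spry1 (-3.00), the fibulin gene Efemp1 (-2.88) and the matrix proteoglycan gene Ogn (-2.77) came next. Calls included 111 genes higher and 41 lower past 4-fold. The deposited ratios of this sample gave 198 higher and 142 lower past 4-fold. In the simulation of the scanner steps a log2 of -2 was recovered as -1.52 but 2 as 1.82, so the processing may add to this imbalance.

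By list, proteases and inhibitors had a median of 0.86 in these scanner values (10 higher, 1 lower, Mmp3 at 3.31). ATF4 and amino acid response genes had a median of 0.72 (5 of 21 higher, 0 lower), with Chac1 at 2.83, the cystine transporter gene Slc7a11 at 2.60 and Trib3 at 1.99. Oxidative and metal stress genes had a median of 0.55 (7 of 19 higher, 0 lower), with the quinone reductase gene Nqo1 5.66-fold higher and the metallothionein gene Mt2 at 2.11. Immediate early genes had a median of 0.43 (5 higher, 2 lower), with Ier3 at 2.98 and Atf3 at 2.53 while Fos was low. SRF and YAP targets had a median of -0.71 (1 higher, 5 lower), with Amotl2 at -1.93, Thbs1 at -1.63 and Vcl at -1.42. Contractile genes had a median of -0.25 (0 higher, 4 lower), with Fhl1 at -1.67 and Myl9 at -1.66. Among 23 NF-kB and inflammatory genes 4 were higher and 8 lower (median -0.64), with Csf2 at 3.18 and Ptgs2, the inducible cyclooxygenase, at 2.97 but the adhesion molecule gene Vcam1 at -2.48. Interferon-stimulated genes had a median of -0.33 (0 higher, 3 lower), namely Ifit2 (-1.41), Ifit1 (-1.34) and Mx2 (-1.23). Collagens had a median of -0.35 (1 higher, 4 lower), Col3a1 at -1.03 against Col18a1 at 1.89.

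The RGD-binding integrin subunits Itgb3 and Itga5 were higher on non-dynamic linear RGD, at 1.54 and 1.43 (SD 0.51), while Itgb5 was at 0.62, Itgb1 at 0.32 and Itgav at 0.12. Fn1 stood at 0.38 and the reference gene Actb at 1.15. The cartilage transcription factor gene Sox9 stood at 2.39. The deposited ratios of this sample gave 1929 genes past 2-fold (904 higher, 1025 lower), of which 1059 were also called in the scanner values.

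Non-dynamic cyclic RGD gave 1670 genes past 2-fold, 828 higher and 842 lower. Mmp13 was 5.94 higher (61.2-fold), Mmp10 4.44 (21.8-fold), Ptpn22 4.26, Areg 3.99 (15.9-fold), the cytokine gene Il1a 3.99, Wnt2 3.97 and Nmu 3.93. The neuropeptide gene Adcyap1 was highest at 6.44, read by 1 probe. The lowest genes with a surface signal on the scanned arrays were Ptx3 (-4.56, 23.6-fold lower), Vip (-4.32), Adamts5 (-4.06), Gdf6 (-3.64) and Spry1 (-3.64). Sh2d4a (-5.64), Ntn4 (-4.64) and Upk3b (-4.32) had such a signal on 1 scanned array at most. Of 21 ATF4 and amino acid response genes 4 were higher and 0 lower (median 0.56), including Slc7a11 (3.03), Chac1 (2.54) and Trib3 (1.83). Of 19 oxidative and metal stress genes 6 were higher and 0 lower (median 0.43), including Nqo1 (2.10). Of 16 collagens 5 were lower and 2 higher (median -0.60), including Col12a1 (-1.47) and Col6a1 (-1.43). SRF and YAP targets had a median of -0.81 (1 higher, 6 lower), with Amotl2 4.00-fold lower and Vcl at -1.72. Interferon-stimulated genes went both ways (5 higher, 2 lower, median 0.29), with Ifi44 at 2.52 and Usp18 at 1.91 against Ifit2 at -1.48. TGF-beta response genes had a median of 0.30 (5 higher, 2 lower), with Pmepa1 at 2.40 and Inhba at 2.04. Itgb3 stood at 1.53 and Itga5 at 0.85. Itgb8 was at -1.29 as the mean of its probes but at 0.26 on its brightest probe.

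**Figure D2:**
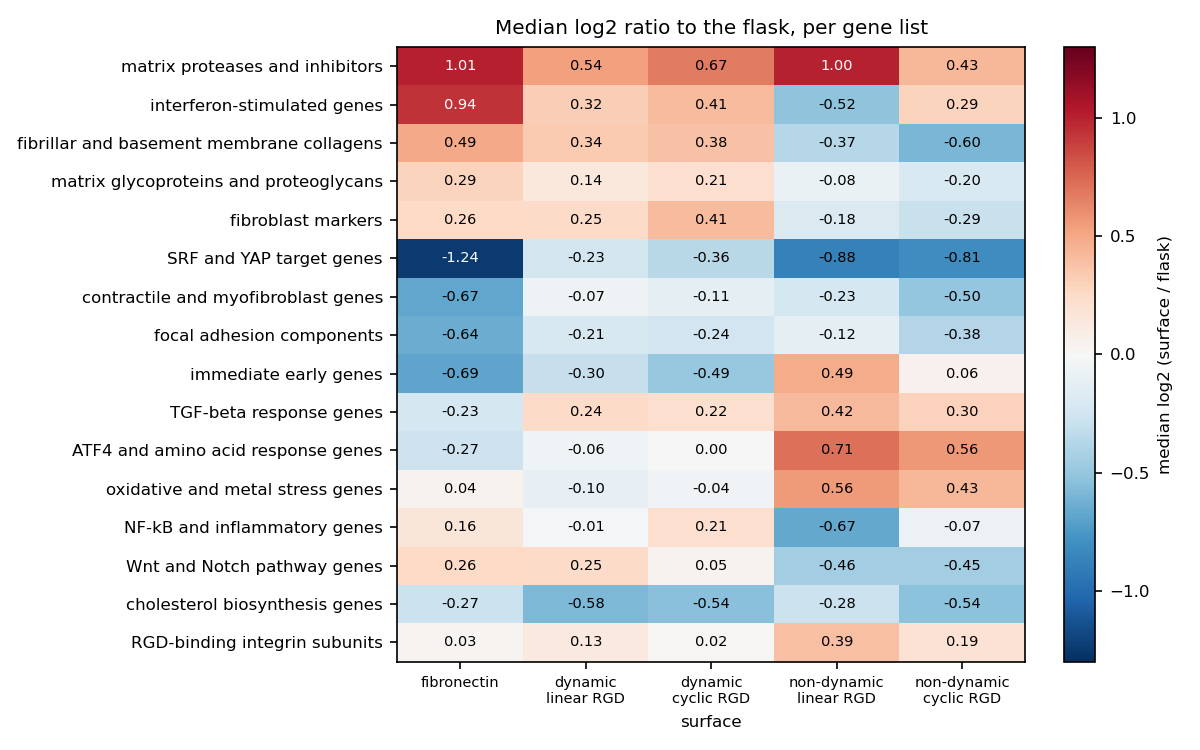
Median log2 of surface over flask (colour) for 16 gene lists (y axis) on each of the 5 surfaces (x axis), from the deposited ratios. Interferon-stimulated genes ran from 0.94 on fibronectin to -0.52 on non-dynamic linear RGD, and ATF4 and amino acid response genes from -0.27 to 0.71.

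Linear and cyclic RGD were compared at matched times. On dynamic surfaces they differed at 110 genes past 2-fold, 73 higher with linear and 37 higher with cyclic peptide, and no fixed list had more than 1 member past 2-fold. This count was 582 without the filter on dim probes (248 higher, 334 lower), 227 after quantile normalization and 59 with both channels above background (48 higher, 11 lower). The 6 genes furthest above on linear RGD were Traf3ip3 (4.60), Olfr381 (2.82), Miox (2.68), Siglecf (1.89), Thoc1 (1.88) and Sfrs15 (1.77), and the 6 furthest below were Arl11 (-2.08), Klrg1 (-2.02), Wnt3 (-1.96), Aox4 (-1.78), Pramel37 (-1.62) and Sec14l4 (-1.49). Of these, Sfrs15, Arl11, Klrg1 and Wnt3 had no flask signal well above background on the scanned arrays, and Olfr381, Siglecf, Aox4 and Sec14l4 had it on at most 2. Among list members, the Notch target Heyl stood at 1.25, Klf2 at 0.96 and Mmp13 at -0.48. The RGD-binding integrin subunits lay between -0.25 (Itgb3) and 0.51 (Itgb6), Itgav being at 0.28, Itga5 at -0.09 and Itgb1 at -0.04. Fn1 was at 0.05 and Actb at 0.91.

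List medians between the dynamic surfaces were small. Immediate early genes (0.16) and p53 targets (0.14) stood above the central 95% of random lists, as did Wnt and Notch genes (0.09). Reference genes (-0.23), oxidative and metal stress genes (-0.15), cholesterol biosynthesis genes (-0.14), lysosome genes (-0.14) and proteases (-0.12) stood below it. The split of 1 RNA within 1 slide gave list medians from -0.08 to 0.19, a range that leaves out any error between slides. With 1 sample per peptide and exposure, no interval could be given for this pair.

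On non-dynamic surfaces, the median of interferon-stimulated genes was lower with linear than with cyclic RGD. Of 25 measured members 9 were lower and 0 higher (median -0.57), among them Ifi44 (-2.30, 4.91-fold lower), Mx2 (-2.09, 4.27-fold lower), Usp18 (-1.91, 3.77-fold lower), Ifit3 (-1.68, 3.19-fold lower) and, shared with the inflammatory list, Cxcl10 (-1.53). Iigp1 was at -2.54 (5.83-fold lower) and the interferon-inducible chemokine gene Cxcl11 at -3.43, with a surface signal well above background on 2 scanned arrays. Cholesterol biosynthesis genes had a median of 0.35 with 1 member past 2-fold, the sterol sensor gene Insig1 (1.12). Lysosome genes (0.35), immediate early genes (0.33, with Klf2 at 1.03), focal adhesion components (0.29), proteases (0.24), collagens (0.23), TGF-beta response genes (0.23), RGD-binding integrins (0.20), endothelial markers (0.19), Wnt and Notch genes (0.18) and contractile genes (0.15) stood above the central 95% of random lists, with at most 1 member past 2-fold each. In the split of the non-dynamic linear RNA itself focal adhesion components (0.19), collagens (0.17), contractile genes (0.16) and lysosome genes (0.12) also stood above it, so for these lists such a percentile can come from technical error alone. NF-kB and inflammatory genes (-0.27) and ribosomal protein genes (-0.18) stood below it.

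In total 139 genes differed past 2-fold between the non-dynamic surfaces, 74 higher with linear and 65 with cyclic RGD. Adcyap1 was lowest at -6.31. Several extreme values rest on weak signals. Slco1a1 (-3.54) and Pkhd1 (-2.58) had no surface signal well above background, and with scanner values for the linear surface they turned to 1.09 and 2.68. Csrp1 (2.25), Pramel1 (2.83) and Arr3 (2.79) had SDs of 1.79, 1.64 and 2.46 between hybridizations, and the high value of Csrp1 came from 1 of the 4. Ntn4 (2.17), Upk3b (2.07), Tatdn2 (2.15) and Selenbp1 (-2.62), which has a near-identical paralog, were the remaining named genes. Integrin subunits lay between 0.01 (Itgb3) and 0.66 (Itga5), with Itgb5 at 0.42, Itgb1 at 0.20 and Itgav at 0.02. With scanner values for the linear surface the count past 2-fold was 391. Those values spread less over genes (SD 0.50) than the sample's deposited ratios (0.65). Subtracting deposited cyclic ratios from them may therefore itself raise the count.

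The linear-minus-cyclic differences of the dynamic and the non-dynamic pair correlated weakly across genes, at 0.14 (bootstrap over genes 0.12 to 0.15, Spearman 0.07). The correlation was 0.0494 without the filter on dim probes and 0.0147 with scanner values for non-dynamic linear RGD. The last value sets scanner values of 1 sample against deposited ratios of the others, and these unlike scales may themselves move it. Both pairs were past 2-fold at 18 genes, 16 in the same direction and 2 opposite. Independent lists of these sizes would share fewer than 1 gene. The interferon-stimulated genes, at -0.57 on non-dynamic surfaces, were at -0.07 on dynamic ones, where Ifi44 was at -0.57. A limma fit over both exposures, chosen after the data were seen, tested linear against cyclic RGD with 2 samples each. At a false discovery rate of 0.05 it called 0 of 19565 genes (198 at an unadjusted p under 0.05). Without a block the exposure difference stays in the residual spread, and in simulation this fit called 0 of 50 genes at a log2 of 1. Its result therefore does not show that the peptides act alike. The fit with the exposure as a block leaves 1 residual degree of freedom, and in simulation it exceeded the nominal false discovery rate. With this block limma gave 1425 genes at an unadjusted p under 0.05 and called 5. Chosen after their values were seen, these were Cdk5r2 (1.79), Lars2 (1.70), LOC673334 (1.74), Wnt3 (-2.12) and 1810046K07Rik (-1.97), each with an adjusted p of 0.0219 from limma, and on the scanned arrays Wnt3 had no flask signal well above background and 1810046K07Rik had it on 2. Between hybridizations of non-dynamic linear RGD, Cdk5r2, Lars2 and LOC673334 had SDs of 1.33, 0.65 and 0.91, far above the median of 0.08, so a technical source of their differences stays open.

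Dynamic against non-dynamic exposure went with larger differences than the form of the peptide. Dynamic and non-dynamic linear RGD differed at 1548 genes past 2-fold (771 higher, 777 lower on dynamic). These samples differ in first ligand, in the fibronectin pattern, in total time and in the 2 h immobilization step with cells present. The design cannot separate these. Of 25 interferon-stimulated genes 12 were higher on dynamic linear RGD and 1 lower (median 0.91), with Mx2 at 3.13, Oasl2 at 2.41, Psmb8 at 2.32 and Ifit3 at 2.16, and Iigp1 at 4.19 (18.3-fold). NF-kB and inflammatory genes had a median of 0.85 (11 higher, 3 lower), Vcam1 at 2.13 but Ptgs2 at -2.94 and Csf2 at -2.74. Collagens had a median of 0.48 (4 higher, 0 lower), with Col11a1 at 2.05, Col1a2 at 1.95 and Col3a1 at 1.56, and matrix glycoproteins a median of 0.40 (9 higher, 0 lower), with the asporin gene Aspn at 3.37 and Postn at 2.78. The fibroblast activation protein gene Fap was at 3.24, the collagen-binding integrin subunit gene Itga11 at 3.73 and the Wnt agonist gene Rspo2 at 3.85 (14.4-fold).

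The medians of ATF4 and amino acid, immediate early, and oxidative and metal stress genes were lower on dynamic than on non-dynamic linear RGD, whereas those of endoplasmic reticulum stress (-0.07, 0 of 19 higher, 2 lower) and heat shock genes (-0.10, 0 of 14 higher, 3 lower) lay within the central 95% of random lists. ATF4 and amino acid response genes had a median of -0.72 (1 higher, 7 lower), with Chac1 at -2.95 and Slc7a11 at -2.85. Immediate early genes had a median of -0.68 (0 higher, 8 lower), with Atf3 at -3.46 and Ier3 at -3.01. Oxidative and metal stress genes (-0.66, 0 higher, 6 lower), lysosome genes (-0.61, 0 higher, 3 lower), TGF-beta response genes (-0.37, Inhba at -2.27), cholesterol biosynthesis genes (-0.28) and hypoxia genes (-0.19) also stood below the central 95% of random lists. Areg was at -3.02, Mmp13 at -2.65 and Itga5 at -1.54. SRF and YAP targets (0.38), collagen processing enzymes (0.39), Wnt and Notch genes (0.49) and fibroblast markers (0.37) stood above it. The largest single values, Ddx4 (6.69), Pkhd1 (5.23), Slco1a1 (4.72) and Asb15 (4.55), had no surface signal well above background on the scanned arrays, where Pkhd1 turned to -0.03 with scanner values. At the low end Mmp12 (-5.61), Htr1a (-4.19) and Atp13a4 (-3.66) had no flask signal well above background, and the chemokine receptor gene Cxcr6 (-3.65, 12.5-fold lower) and Celsr1 (-3.49, 11.3-fold lower) followed. Usp17lb was at -4.32, and on the scanned arrays of non-dynamic linear RGD it was at least 2.01-fold above a flask signal not well above background.

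Dynamic and non-dynamic cyclic RGD differed at 1235 genes, 693 higher and 542 lower on dynamic. Collagens had a median of 0.85 (7 of 16 higher, 0 lower), with Col1a2 at 2.09, Col6a1 at 1.79, Col11a1 at 1.58 and Col3a1 at 1.41. Matrix glycoproteins had a median of 0.55 (10 higher, 0 lower), with Aspn at 3.04 and Postn at 2.69, fibroblast markers 0.58 (4 higher, 0 lower) with Fap at 3.64 (12.5-fold), SRF and YAP targets 0.56 (3 higher, 0 lower) and contractile genes 0.39 (4 higher, 0 lower) with Myl9 at 1.44. Interferon-stimulated genes had a median of 0.34 (4 higher, 1 lower), with Psmb8 at 1.40 and Ddx58 at 1.36. ATF4 and amino acid response genes had a median of -0.50 (1 higher, 5 lower), with Chac1 at -2.54 and Slc7a11 at -2.13, immediate early genes -0.45 (0 higher, 5 lower) with Atf3 at -3.07 and Ier3 at -2.73, and oxidative and metal stress genes -0.25 (0 higher, 5 lower). Collagen processing enzymes (0.31) and Wnt and Notch genes (0.22) stood above the central 95% of random lists. The bombesin receptor gene Grpr (4.31, 19.8-fold), Rspo2 (3.80, 13.9-fold), Rerg (3.73, 13.3-fold) and the chemokine gene Ccl11 (3.64) were among the highest, and Areg (-3.60, 12.2-fold lower) and Celsr1 (-3.42, 10.7-fold lower) among the lowest. Adcyap1 (-6.16), Usp17lb (-4.97), Traf3ip3 (-4.69) and Cyp1a1 (-3.74) were also low, and Ddx4 (4.61) and Ccl11 had no surface signal well above background on the scanned arrays. Csf2 was at -2.86 and Ptgs2 at -2.54. Mmp13 was at -2.11 but turned to 0.50 after quantile normalization, which by construction gives the top ranks of both columns, where Mmp13 lies, like values.

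The dynamic-minus-non-dynamic differences with linear and with cyclic peptide, which share no surface sample, correlated at 0.77 across genes (bootstrap over genes 0.76 to 0.78, Spearman 0.66). Of the genes past 2-fold in both, 834 went in the same direction (470 higher, 364 lower) and 3 in opposite directions, against 27.3 and 21.4 shared by independent lists. A limma fit over both peptides, chosen after the data were seen, tested dynamic against non-dynamic RGD with 2 samples each and called 2812 of 19565 genes at a false discovery rate of 0.05, 1601 higher and 1211 lower, of which 1119 were past 2-fold. With the peptide as a block it called 3910. Without the block Fap (3.44, adjusted p = 0.00114), Postn (2.73, adjusted p = 0.00114) and Rspo2 (3.82, adjusted p = 0.00114) were higher on dynamic surfaces by limma, and Atf3 (-3.27, adjusted p = 0.00114), Chac1 (-2.75, adjusted p = 0.00124) and Areg (-3.31, adjusted p = 0.00125) were lower. Iigp1 (2.79) had an adjusted p of 0.0629 without and 0.0114 with the block, and Ifi44 (0.97) one of 0.417 and 0.0966. The p-values treat linear and cyclic RGD as replicates of 1 exposure. In simulation, without and with the block, unchanged genes made up a larger share of the calls than the nominal false discovery rate. Slides and scan days of 4 samples are not known here, so no hybridization batch was examined.

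**Figure D3:**
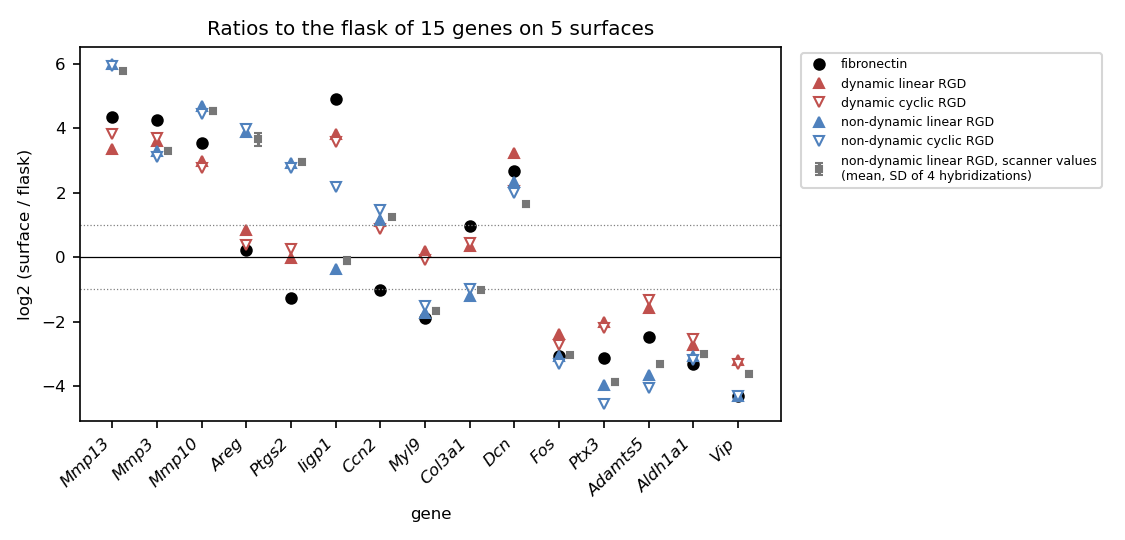
Log2 of surface over flask (y axis) for 15 genes on the 5 surfaces, with circles (fibronectin) and triangles (RGD, open for cyclic) from the deposited ratios, grey squares for the scanner mean of non-dynamic linear RGD with the SD of 4 hybridizations, and dotted lines at 2-fold. Iigp1 ran from 4.92 on fibronectin to -0.38 on non-dynamic linear RGD, whereas Mmp13 was 3.34 or higher on every surface.

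Against fibronectin, the dynamic surfaces had higher medians of contractile and of SRF and YAP target genes. On dynamic linear RGD 386 genes differed past 2-fold (123 higher, 263 lower) and on dynamic cyclic RGD 426 (124 higher, 302 lower). SRF and YAP targets had medians of 0.90 (7 higher, 0 lower) and 0.84 (9 higher, 0 lower), with the connective tissue growth factor gene Ccn2 at 2.16 and 1.91 and Thbs1 at 1.28 and 1.35. Contractile genes had medians of 0.56 and 0.60 (7 higher, 0 lower on both), with Myl9 at 2.08 and 1.81, the smooth muscle actin gene Acta2 at 1.80 and 1.48 and Tagln at 1.74 and 1.52. Focal adhesion components had medians of 0.37 and 0.36 with at most 1 member past 2-fold. Interferon-stimulated genes had medians of -0.35 and -0.34, each with 1 member lower. Proteases and inhibitors were at -0.47 on dynamic linear RGD (2 higher, 2 lower) and at -0.28 on dynamic cyclic RGD, where the median turned to 0.10 after quantile normalization. Matrix glycoproteins were at -0.19 on dynamic linear RGD and turned to 0.05 there. Slc40a1 (-2.81), Adamts15 (-2.78) and Ppp1r3c (-2.64) were among the lowest on dynamic linear and Lrrc17 (-2.62) on dynamic cyclic RGD. The p53 targets were at -0.32 and -0.33 (0 higher, 2 lower on both), NF-kB genes at 0.28 and 0.42 and lysosome genes at -0.42 and -0.22. Dynamic surfaces were harvested later than fibronectin and went through the immobilization step, so times and handling differ here.

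The non-dynamic surfaces, harvested at 24 h like fibronectin, differed most from it. The fibronectin surface was also patterned, so ligand and pattern cannot be separated in this comparison. Non-dynamic linear RGD differed at 2534 genes (1206 higher, 1328 lower) and non-dynamic cyclic RGD at 1732 (692 higher, 1040 lower). Of 25 interferon-stimulated genes, 15 were lower against 1 higher on linear (median -1.26; Mx2 -3.58, Oasl2 -3.22, Ifi44 -3.08, Ifit1 -3.01, and Iigp1 -5.30) and 7 against 1 higher on cyclic RGD (median -0.78; Psmb8 -1.68, Oasl2 -1.59). Matrix glycoproteins were at -0.56 (1 higher, 11 lower) and -0.67 (1 higher, 12 lower), with Aspn at -4.85 and -4.11 and Postn at -3.27 and -3.07. Collagens were at -0.51 (1 higher, 5 lower) and -0.76 (0 higher, 6 lower), and fibroblast markers at -0.41 and -0.77, with Fap at -4.96 on both. Immediate early genes were at 1.17 (12 of 23 higher, 0 lower) and 0.62 (9 higher, 0 lower), with Ier3 at 3.42 and 3.30 and Atf3 at 3.38 and 3.07. ATF4 and amino acid response genes had 11 of 21 members higher and 1 lower on linear and 8 higher and 1 lower on cyclic RGD (median 0.77), with Chac1 at 3.05 and 2.81. Oxidative and metal stress genes were at 0.63 (8 higher, 0 lower) and 0.68 (5 higher, 0 lower), and TGF-beta response genes at 0.72 (8 higher, 1 lower) and 0.42 (7 higher, 2 lower), with the activin subunit gene Inhba at 3.16 on linear RGD. Focal adhesion components were at 0.58 (5 higher, 0 lower) and 0.28 (1 higher, 1 lower), and SRF and YAP targets at 0.45 and 0.50 (3 higher, 1 lower on both). NF-kB genes were at -0.51 on linear RGD (5 higher, 7 lower). Ptgs2 was highest or near it on both, at 4.20 and 4.05, with the cadherin gene Cdh6 at 4.11 and 3.70, and Ccl11 (-6.11 and -5.65), Lrrc17 (-6.06 and -5.19) and Ppp1r3c (-6.23 and -4.97) were the lowest, Ccl11 without a surface signal above background on the scanned arrays. Itga5 was at 2.35 and 1.68 and Itga11 at -4.46 on linear RGD. Jag1 was at 3.13 and Notch3 at -3.19 there. A limma fit of the 3 surfaces begun on fibronectin against the other 2, chosen after that split was seen in these data, called 3293 of 19565 genes at a false discovery rate of 0.05, 1848 higher and 1445 lower. Its groups come from these same data and hold the 4 RGD samples of the dynamic against non-dynamic fit, so the count is no separate support. In simulation it also exceeded the nominal false discovery rate, and a hybridization batch was not examined.

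Across genes, fibronectin correlated with dynamic linear RGD at 0.80 and with dynamic cyclic RGD at 0.77, but with non-dynamic linear RGD at 0.33 and non-dynamic cyclic RGD at 0.47. The dynamic surfaces correlated at 0.82 with each other and the non-dynamic surfaces at 0.88. Simulated unchanged surfaces with a shared flask correlated at 0.50, with a covariance of 0.13, and observed covariances ran from 0.10 to 0.36. The simulated correlation was fixed by giving the flask the same spread per gene as a surface, so it is no measured chance level. Part of each correlation may come from the shared flask, and genes are not independent replicates.

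Several lists had medians near the flask, although some stood outside the central 95% of random lists. In the deposited ratios none of 26 ribosomal protein genes and none of 25 oxidative phosphorylation genes was past 2-fold on any surface, with medians between -0.14 and 0.20, ribosomal protein genes standing above the central 95% on both cyclic surfaces. DNA replication genes (27 measured) had medians between -0.14 and 0.25, the highest above the central 95% on non-dynamic cyclic RGD, and mitosis genes (28 measured) between -0.43 on fibronectin, where 3 were lower and the list stood below the central 95%, and -0.13. The 13 measured reference genes had medians between -0.14 and 0.02, although Actb ranged from -0.07 on dynamic cyclic to 1.23 on non-dynamic linear RGD. The 9 RGD-binding integrin subunits had medians between 0.02 and 0.39, the highest above the central 95% on non-dynamic linear RGD in the deposited but not in the scanner values, and the 11 other integrin subunits between -0.09 and 0.21, in which Itga11 was at 3.79 on fibronectin. Itgb3 was at 1.03 on fibronectin and 0.99 on dynamic cyclic RGD, and Itga5 at -0.84 on fibronectin. Adipogenic genes had medians between -0.05 and 0.08, hypoxia and glycolysis genes between -0.14 and 0.11 and growth factors and receptors between 0.09 and 0.21, growth factors standing above the central 95% on both dynamic surfaces. On each non-dynamic surface 6 of 28 hypoxia and glycolysis genes were higher and 1 lower, against 0 higher and 1 lower on each dynamic surface. Of 30 growth factor and receptor genes 10 were higher and 4 lower on non-dynamic linear and 8 higher and 4 lower on non-dynamic cyclic RGD. Endoplasmic reticulum stress genes had medians between -0.38 and -0.13, below the central 95% of random lists on every surface except non-dynamic linear RGD. Heat shock genes had medians between -0.45 and 0.01 and stood below it on fibronectin and both dynamic surfaces. The p53 targets had medians between -0.45 and -0.10 and stood below it on both dynamic surfaces and on non-dynamic cyclic RGD, although 4 of 20 were higher and 3 lower on non-dynamic linear and 2 higher and 3 lower on non-dynamic cyclic RGD.

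As lists, markers of other cell types mostly lay near the flask. Medians lay between -0.03 and 0.25 for epithelial, 0.04 and 0.31 for macrophage and leukocyte, 0.01 and 0.24 for endothelial, 0.02 and 0.14 for neuronal and glial, and -0.03 and 0.11 for skeletal muscle markers. Cartilage and bone markers had a median of 0.44 on fibronectin, above the central 95% of random lists, with Spp1 at 3.30 and Mgp at 3.15, and 0.06 to 0.16 elsewhere. The 16 fibroblast markers had medians of 0.26, 0.25 and 0.41 on fibronectin, dynamic linear and dynamic cyclic RGD, and of -0.18 and -0.29 on the non-dynamic linear and cyclic surfaces.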

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

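All tests of explanations in this part, and the wording of the rule for differing effects, were chosen after the results were seen.

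The first pattern is that surfaces on which cells began on fibronectin stood apart from those on which cells began on RGD. Total time on the surface would place fibronectin, harvested at 24 h, with the non-dynamic surfaces. Its lowest correlation across genes with a dynamic surface lay 0.30 (0.28 to 0.32) above its highest with a non-dynamic one. These correlations define the pattern, so the gap is no separate test. It shows that the grouping did not follow total time, but a share of time in the dynamic against non-dynamic differences stays open. Dynamic minus non-dynamic linear RGD and fibronectin minus non-dynamic cyclic RGD, which share no sample, correlated at 0.74 (0.73 to 0.75; 0.72 for the other pairing), but the covariances of the surfaces that define the pattern already give that value, so it decides nothing about the ligand met at seeding. The ligand met at seeding therefore stays open, as do the confined pattern of the fibronectin surfaces and a hybridization batch, which no label names but which was not excluded, since only 1 sample has a known slide and scan day here. Separate cultures seeded on RGD in that same confined pattern, with slides shared between groups, would test the first ligand, and no such sample exists here.

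The second pattern is the lower level of interferon-stimulated genes on non-dynamic linear than on non-dynamic cyclic RGD, at -0.57 in the median. The authors' processing of the linear sample is an unlikely sole source, since scanner values in its place gave -0.67 with 20 of 25 members below 0. In the deposited ratios 23 were below 0. The scanner values differ in scale from the deposited cyclic ratios, and the authors' processing of the cyclic sample was not examined. A linear against cyclic difference of this size that also holds on dynamic surfaces is argued against by a median of -0.0665 there, although 17 of 25 members were below 0. The interferon state of single cultures stays open, because with 1 sample per surface no spread between separate cultures exists here. A difference between the peptides limited to directly seeded cells also stays open and was not tested.

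The third pattern lies in control probes that no comparison used. The median of spike-in RNA, added before labelling, was brighter in the surface channel, by 2.70 in log2 as the mean over 4 hybridizations (2.60 to 2.78), but single spike-ins ran from -0.14 to 4.54. A dye bias shared by all probes is argued against, because before loess the spike-in median lay 2.75 to 2.97 above the median of all other probes. More spike-in RNA per labelled RNA in the surface channel stays open, since observed and designed spike-in ratios correlated at 0.959 or higher around a log10 intercept of 0.74 (5.50-fold) or higher, but any uniform shift leaves that correlation as it is and the intercept restates the pattern. The slope of observed on designed spike-in log ratios was only 0.67 to 0.73 per the scanner headers, so these ratios spread less than designed. No biological explanation was tested.

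The following genes lay past 2-fold in opposite directions, or lists on opposite sides of the random lists, under the same contrast in both settings, and these differences were not tested, since each rests on 1 sample per group. For linear minus cyclic RGD, Sec14l4 was at -1.49 on dynamic and 1.16 on non-dynamic surfaces, a gap of -2.66, and Upk3b at -1.21 and 2.07, a gap of -3.28; both were dim. In the same contrast matrix proteases and inhibitors had medians of -0.12 and 0.24, a gap of -0.35. Cholesterol biosynthesis genes had -0.14 and 0.35, a gap of -0.49. Lysosome and autophagy genes had -0.14 and 0.35, a gap of -0.48. For dynamic minus non-dynamic, Cxcl11 was at 1.92 with linear and -1.45 with cyclic RGD, a gap of 3.38. Selenbp2 was at 1.05 and -1.27, a gap of 2.33, and Sec14l4 at -1.37 and 1.28, again a gap of -2.66. A search restricted to genes above background in both channels gave 0 such genes, and the search was then widened to all measured genes and to lists on opposite sides of the central 95% of random lists.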

How the results depend on the processing

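Quantile normalization of the gene lists and the limma fits that pool surfaces were chosen after seeing the data. With the peptide as a block, paired over linear and cyclic RGD, limma called 3910 genes for dynamic against non-dynamic RGD against 2812 without it, and with the exposure as a block it called 5 genes for linear against cyclic RGD against 0 without it. For differences between single surfaces no paired analysis was possible because each group has 1 sample, and averaging within slides was not run because 1 slide held all 4 scanned arrays. The cause of the changes below was not tested, except that a filter adds or removes the genes counted. Quantile normalization also gives the columns 1 distribution, and scanner values for 1 sample mix sources of unlike scale.

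For non-dynamic linear RGD against the flask, the 1064 genes past 2-fold became 1878 with the scanner software's log ratio and 1929 with the deposited column, 1102 without background subtraction, 1124 with median centring, 1011 without a filter, 1096 with both channels above background, 1395 with the brightest probe and 1036 to 1124 without each hybridization in turn. Without a filter on dim probes, counts from deposited ratios became 2235 for fibronectin, 1519 for dynamic linear and 1361 for dynamic cyclic RGD, 582 between the dynamic and 587 between the non-dynamic surfaces, and 893 and 876 for dynamic linear and cyclic RGD against fibronectin. The correlations of differences became 0.0494 for linear minus cyclic and 0.61 for dynamic minus non-dynamic. The filter also moved the split: without it, higher against lower genes were 823 and 1412 on fibronectin, 442 and 1077 on dynamic linear, 429 and 932 on dynamic cyclic, 877 and 1850 on non-dynamic linear and 821 and 1515 on non-dynamic cyclic RGD, 248 and 334 between the dynamic surfaces, and 146 and 104 on all 5 surfaces. With both channels above background the dynamic surfaces differed at 59 genes (48 higher with linear, 11 lower), the non-dynamic ones at 86, and the second correlation was 0.80. Quantile normalization gave 1147 genes on dynamic linear, 1140 on dynamic cyclic and 1274 on non-dynamic linear RGD, 227 between the dynamic and 86 between the non-dynamic surfaces, and correlations of 0.16 and 0.74. Scanner values for non-dynamic linear RGD gave 1066 genes against the flask, 391 between the non-dynamic surfaces (38.9% higher against 53.2%), 112 on all 5 surfaces, and correlations of 0.0147 and 0.63.

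Results that turned were Cdh5 (-1.05 to 0.38) and Vim (-1.42 to 0.10) on fibronectin, Itgb8 on non-dynamic cyclic RGD (-1.29 to 0.26) and Vim on dynamic linear (1.06 to -0.14) and dynamic cyclic RGD against fibronectin (1.08 to -0.10) with the brightest probe. With scanner values for non-dynamic linear RGD, Pkhd1 (-2.58 to 2.68) and Slco1a1 (-3.54 to 1.09) turned between the non-dynamic surfaces, and Itga2 (-2.02 to 0.0408) and Pkhd1 (5.23 to -0.0339) between dynamic and non-dynamic linear RGD. Quantile normalization turned Mmp13 between dynamic and non-dynamic cyclic RGD (-2.11 to 0.50), matrix glycoproteins on dynamic linear RGD against fibronectin (-0.19 to 0.046) and proteases on dynamic cyclic RGD against fibronectin (-0.28 to 0.10). Single-gene results were held against the hybridization SD of non-dynamic linear RGD, used for every surface because the others have none here, and lists against the standard error over members. That SD holds no error between slides. Quantile normalization moved 1318 and left 1216 within that size, the brightest probe moved 659 and left 1556, and scanner values moved 300 and left 325. Of 207 list medians outside the central 95% of random lists, 195 stayed on the same side without a filter and 198 with unmatched lists. Of 194 from deposited ratios, 194 did so with centring and 179 with quantile normalization, and 0 changed to the opposite side. Signal over background limits the dim genes, whose detection was seen on 1 sample's arrays only.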

Other observations

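No test was run in this part, and the gene below was singled out after its values were seen. Adcyap1, which encodes the neuropeptide PACAP, was at 6.44 (86.7-fold) on non-dynamic cyclic RGD and between -0.04 and 0.28 on the other 4 surfaces in the deposited ratios. It was read by 1 probe, which was well above background in both channels on all 4 scanned arrays of non-dynamic linear RGD, where its scanner value was 0.09 (SD 0.09). The related neuropeptide gene Vip was at -4.32 on the same surface.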
